A study of Drosophila melanogaster with 22 samples.

How the data were processed

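RNA-seq was made from small pools of larval Drosophila brain cells, and 22 libraries in 8 groups were used. Larvae were raised at 25 °C, brains of 30 larvae were dissected and dissociated with enzymes, and a robotic sorter took GFP-labelled cells 10 at a time, per the labels' protocols. RNA was extracted with a PicoPure kit, amplified with the Ovation RNA-Seq System V2 and made into libraries with an Encore kit, per the labels' protocols. Libraries held 47 to 124 cells and each had received ERCC mix, in volumes that differed for the neuron libraries, per the labels. Neuroblasts were taken at 50 h after hatching and neurons and glia from wandering larvae, per the labels. Fly genotypes, drivers of the GFP label, read strand, and what the wait and the washes consisted of are not given in the sources used here. Whether replicate libraries came from separate preparations is not given in the sources used here either.

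The deposited count table holds reads per gene, made by the authors with CASAVA, cutadapt 1.7.1, Bowtie2 2.1.0, STAR 2.4.0i and HTSeq 0.6.1p1 on the builds mm10 and dm3, per the submitters' processing notes, which do not give the role of mm10. The deposited TPM table was made by the authors from the same counts. Among 2397 genes with 50 or more counts in every library, the ratio of count to TPM departed from a constant per gene and library by at most 1.78e-15 log2 units. Each TPM column summed to 1000000 and held no ERCC values. The count table has 15339 gene entries, 92 ERCC entries (77 with a count) and an entry with no name, and 14190 genes had a count. Entries without a gene stayed out of library sizes and tests. Reads outside annotated genes came to 7.92 to 23.8% of all counts in the table, ERCC counts included, ambiguous reads to 1.03 to 1.76%, and the entry with no name held at most 17 counts. Gene names, positions, biotypes and GO terms were the authors' annotation columns (dm3), and no position from another build was used.

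Libraries held 3150371 to 14282246 gene counts and 8958 to 11779 detected genes, and ERCC counts were 0.120 to 9.75% of gene plus ERCC counts. The genes CR41602 and CR40677 together held 10.1 to 31.9% of gene counts, with group means of 22.7% in glia, 21.9% in neurons and 10.9% in pooled neuroblasts. Replicates correlated on log CPM at 0.908 to 0.950 in the neuroblast groups, 0.710 in neurons and 0.645 in glia. Pairs of replicate libraries were compared by chi-square over degrees of freedom (10.5 to 167), so no library was a second copy of another of its group; libraries of different groups were not compared in this way. Reads shared between paralogs, as among E(spl) or ribosomal protein genes, and reads of overlapping genes on opposite strands were not separated here.

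Genes were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr) in R 4.3.3. A fit of pooled neuroblasts, neurons and glia served the cell type comparisons, a fit of the 4 standard neuroblast groups the lineage comparisons, and a fit of the 3 mushroom body groups the handling comparisons. Biological coefficients of variation were 0.80, 0.41 and 0.42 with 4, 8 and 6 residual degrees of freedom. Adjusted p is Benjamini-Hochberg over the tested genes of a comparison, called below 0.05. For a lineage against both others a gene needed both contrasts to pass with the same sign, with the larger p and the smaller change kept, set to 0 where the 2 changes differ in sign. Medians of lists and of all genes in those comparisons are of the mean of the 2 changes. List tests there set the lineage against the mean of the other 2, so a list can pass without standing apart from each of them. CPM are TMM-scaled within the libraries of each fit, while ranges in captions and the closing section are scaled over all 22 libraries, so they differ slightly. Where a group had no count, the fold is a lower limit that sets that group at 3 counts. Where it had 1 to 3 counts, the ratio has a 95% Poisson interval of the counts. Both use counts summed over the libraries of a group, so they can differ from the ratio of the mean CPM. The interval covers counting error alone, not amplification or the spread between libraries.

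Gene lists, 23 in all, were fixed before the data were examined and tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation. Adjusted p of lists runs over 253 list tests. Of these 120 passed with the preset correlation and 18 with the estimated one. Which lists the report describes was chosen after the results were seen. The report names the 6 tested genes with the largest change in each direction among called genes that passed a filter. The filter asked for a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups compared. The separation of these genes between groups so follows from the rule. Also named are up to 4 called members of each described list, and markers set in advance for the cell type and lineage comparisons. This rule was written before the data were examined. Genes named outside the rule (list members that went against their list, CR43283, and those of the closing section) were chosen after their values were seen. GO terms of 10 to 300 tested genes were tested with Fisher's exact test (scipy 1.17.1, Benjamini-Hochberg over all terms, directions and comparisons), which was also chosen after seeing the data. Fisher's test takes genes as independent, so its p values do not allow for genes that change together.

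RNA per cell was the ratio of gene counts to ERCC counts, times the spike-in volume, divided by the number of cells. It was compared by an exact permutation test of the mean of log2 values. Alternatives set before the data were examined were RLE scaling, no low-count filter, DESeq2 1.42.0, limma on log2 of the deposited TPM plus 1, all libraries in 1 fit, a replicate block, each library left out in turn and, for cell types, scaling by spike-in counts per cell. The spike-in scaling of lineage and handling comparisons was added after seeing the data.

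Recovery was tested on counts simulated from the mean levels, depths and dispersions of the real libraries, with 50 genes changed at each size. Changed genes were drawn from those above a minimum expected count. In the cell type comparisons far fewer genes changed than were called in the real data. The adjusted p cutoff was so stricter there, and these rates need not carry over. In neuroblast against neuron 8% of 4-fold, 22% of 8-fold and 74% of 64-fold changes were called, with 2 of 9248 unchanged genes. In neuron against glia 4%, 16% and 66% were called, with 1 of 9305 unchanged genes. In mushroom body against pooled neuroblasts 34% of 2-fold, 66% of 4-fold and 90% of 8-fold changes were called, with 7 of 8656 unchanged genes. In mushroom body against both lineages these were 32%, 66% and 82% with 3 of 8679, and after 3 washes 24%, 66% and 90% with 10 of 8215. No call had the wrong sign, and the 64-fold size was added after a first run. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.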

Results

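RNA was sequenced from small pools of GFP-labelled cells that a robotic sorter picked from dissociated brains of Drosophila larvae. The 22 libraries fall into 8 groups. Pooled neuroblasts of all lineages, mushroom body neuroblasts, antennal lobe neuroblasts and type II neuroblasts have 3 libraries each, and neurons and glia have 2 each. A further 3 mushroom body libraries carry the label of a 2 h wait and 3 the label of 3 washes. Neuroblasts, the stem cells of the brain, were taken at 50 h after hatching, while neurons and glia came from wandering larvae. A library was made from 47 to 124 cells and held 3150371 to 14282246 counts in annotated genes, with 8958 to 11779 genes detected. The noncoding gene CR43283 (chromosome 3R, 7073825 to 7081845 in dm3) held 14.8 ± 1.96% of all gene counts in pooled neuroblasts (SD, n = 3), 0.308 ± 0.0522% in glia and 0.00583 ± 0.00299% in neurons (SD, n = 2). Nothing states that replicate libraries came from separate animals beyond pooled preparations, so each p value measures the spread between these samples.

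The ERCC spike-in answers how much RNA a neuroblast held relative to a neuron or a glial cell. Neuroblasts held the most RNA per cell and glia the least. Over the 12 standard neuroblast libraries the geometric mean of RNA per cell was 2.84-fold that of the 2 neuron libraries (log2 difference 1.50, exact permutation p = 0.0220). Against the 2 glia libraries it was 10.2-fold (log2 difference 3.35, exact permutation p = 0.0220). Each p is the smallest that 91 splits of the libraries allow. With the 3 pooled neuroblast libraries alone the log2 differences were 1.49 and 3.33, each with exact permutation p = 0.200, the smallest that 10 splits allow. On a scale where the neuron mean is 1, pooled neuroblasts stood at 2.75 ± 0.275 (SD, n = 3), antennal lobe neuroblasts at 2.72 ± 0.249 and mushroom body neuroblasts at 1.699 ± 0.342. Type II neuroblasts stood at 5.26 ± 3.13, with their first library at 8.87, and glia at 0.275 ± 0.0566 (SD, n = 2). Mushroom body libraries with the 2 h wait stood at 1.93 ± 0.429 and those with 3 washes at 3.02 ± 0.110. The measure so also moved between handling groups of 1 lineage. Neurons and glia came from wandering larvae, so larval age changed with cell type here as well. The spike-in volume differed for neurons per the labels and was divided out, so an error in the recorded volume would move every neuron value.

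**Figure D1:**
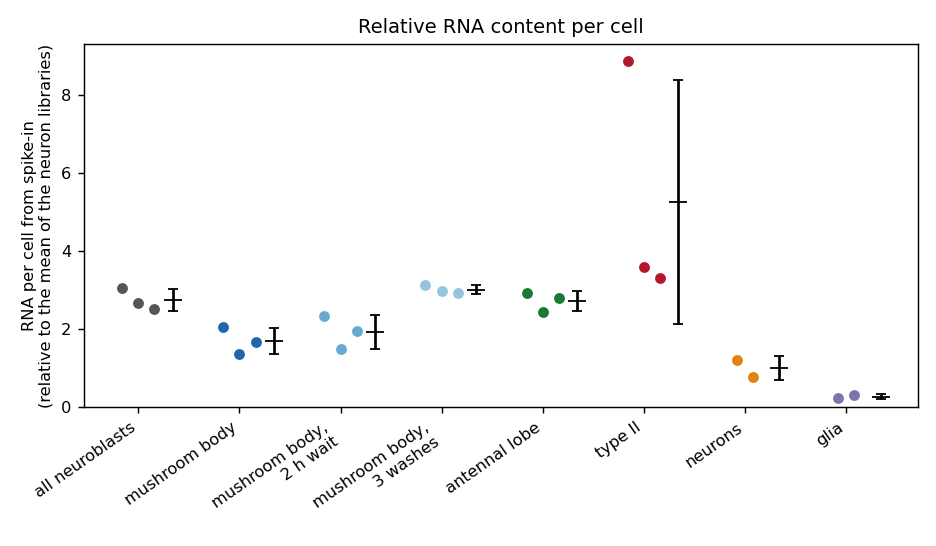
RNA per cell from the ERCC spike-in in each library, relative to the neuron mean. The 2 glia libraries lay at 0.235 and 0.315 and the pooled neuroblasts at 2.52 to 3.05. Type II neuroblasts spread from 3.31 to 8.87. Dots are libraries and the black mark is the mean with its SD.

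The first comparison asked which genes tell pooled neuroblasts from neurons. Most stem cell factors and most cell cycle genes were higher in neuroblasts, and most genes of synapses and transmitters were higher in neurons. The list calls of the stem cell factors (adjusted p = 0.206) and the cell cycle genes (adjusted p = 0.165) were lost with an estimated correlation. Several of these genes had no count at all in the other cell type. Of 9855 genes tested, 1007 were higher in neuroblasts and 1431 lower, and with scaling by spike-in counts per cell 3301 were higher and 828 lower. The median over all genes was 0.18 with the main scaling and 1.94 with the spike-in scaling.

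The stem cell factor wor, a zinc finger protein of the Snail family (FBgn0001983, chromosome 2L, 15423293 to 15425585 in dm3), stood at 512 ± 62.1 CPM in neuroblasts (SD, n = 3) and 0.423 ± 0.208 in neurons (SD, n = 2), a log2 change of 10.08 ± 0.56 (SE, adjusted p = 1.34e-05). The proneural gene ase (chromosome X, 354533 to 357209 in dm3) stood at 169 ± 33.3 CPM and had no count in neurons, so it was at least 596-fold higher with a floor of 3 counts over the neuron group. The basic helix-loop-helix factor dpn stood at 454 ± 33.0 CPM against 0.486 ± 0.485 (log2 change 10.06 ± 1.49, adjusted p = 0.00162). Among 17 neuroblast identity factors 13 rose, 2 fell and 2 did not pass, with 13 up and 2 down when adjusted over the list alone. The list call had adjusted p = 2.42e-07, and adjusted p = 0.206 with an estimated correlation. Other members that rose were grh (log2 change 7.30) and klu (6.84), while the early temporal factor Kr fell by 5.91. The other that fell, hb, had no count in neuroblasts and stood at 11.7 ± 2.15 CPM in neurons. The Snail family gene sna and the chromatin assembly gene Caf1-180 had no count in neurons and were at least 441-fold and at least 691-fold higher. The Notch target genes E(spl)m7-HLH (172 CPM) and E(spl)mbeta-HLH (120.0 CPM) also had no count in neurons.

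The polarity gene baz, the fly Par-3, stood at 91.9 ± 8.37 CPM in neuroblasts and had no count in neurons (at least 325-fold). The spindle gene mud stood at 238 ± 17.2 CPM against 0.138 ± 0.195, a ratio of 2533-fold (454 to 100070), with a 95% counting interval since neurons held 3 or fewer counts. The adaptor mira, which carries fate determinants to the daughter cell, rose by 5.99 (adjusted p = 0.0181), l(2)gl by 3.47 and loco by 6.38. Of 18 genes of asymmetric division 10 rose, 1 fell and 7 did not pass, against 13 up and 1 down when adjusted over the list alone. The kinase gene aPKC was the member that fell, by 1.06. That list had adjusted p = 4.89e-05, and adjusted p = 0.0812 with an estimated correlation. The cell cycle list was nearly complete, as 36 of 43 genes rose (39 adjusted over the list alone) and 7 did not pass. Its call had adjusted p = 1.77e-19, and adjusted p = 0.165 with an estimated correlation. The B-type cyclin CycB3 (chromosome 3R, 20694075 to 20696617 in dm3) stood at 1401 ± 263 CPM against 1.39 ± 1.16 (log2 change 10.11 ± 0.63). The anaphase gene fzy rose by 8.53, the replication clamp gene mus209 by 6.73 and the nucleotide reductase gene RnrL by 5.79.

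The vesicle gene n-syb, the neuronal synaptobrevin (FBgn0013342, chromosome 3L, 1632193 to 1637752 in dm3), stood at 1.50 ± 0.243 CPM in neuroblasts and 3045 ± 300.1 in neurons, a log2 change of -10.97 ± 0.42 (adjusted p = 4.12e-06). Of 35 genes of neuronal differentiation and synapse 32 fell in neuroblasts (32 adjusted over the list alone), 2 did not pass and pros alone rose, by 5.12. As a list these had adjusted p = 4.88e-27, and adjusted p = 0.0312 with an estimated correlation. The complexin gene cpx changed by -8.28, the cadherin gene CadN by -7.64 and elav by -2.61. The nicotinic receptor gene nAcRalpha-96Aa was 24979-fold (4482 to 986710) higher in neurons by its counting interval. Of 12 transmitter genes 11 fell and 1 did not pass, and all 12 fell when adjusted over the list alone (adjusted p = 1.09e-08, and adjusted p = 0.0423 with an estimated correlation). The transmitter transport and synthesis genes VAChT (chromosome 3R, 14531174 to 14544638 in dm3), VGlut, Gad1 and Vmat stood at 693, 1226, 703 and 2483 CPM in neurons. None of them passed a mean of 1.07 CPM in neuroblasts. The prohormone convertase gene amon, the guidance receptor gene robo3 and the genes CG34362, CG42750, CG10830 and mun had no count in neuroblasts. They stood at 470.3, 368, 722, 550.0, 379 and 414 CPM in neurons. The glial factor repo was low in both types, at 2.22 ± 0.203 CPM in neuroblasts and 0.276 ± 0.391 in neurons, a ratio of 11.8-fold (3.12 to 99.4). Cell type and larval age changed together in this comparison. The 2 neuron libraries correlated at r = 0.710, against 0.940 to 0.950 among pooled neuroblasts, and CR41602 and CR40677 held 21.9 ± 14.2% of gene counts in neurons and 10.9 ± 0.731% in pooled neuroblasts.

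**Figure D2:**
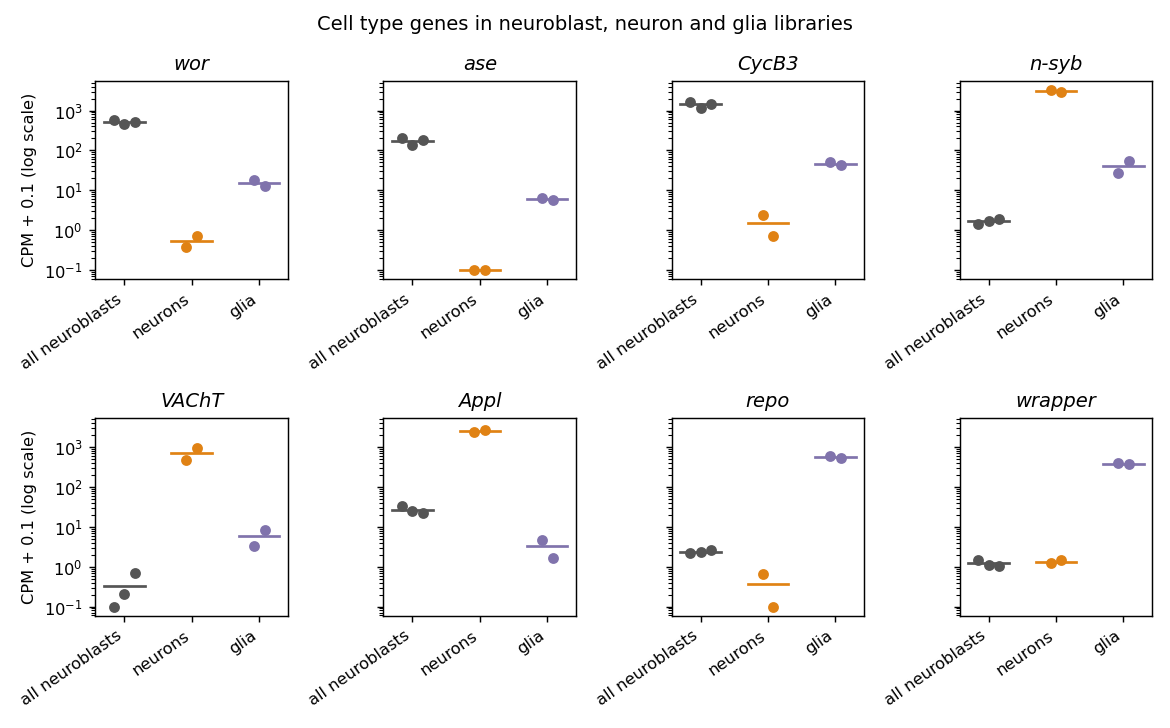
Genes of neuroblasts, neurons and glia in each library of the 3 cell types. The neuroblast gene wor lay at 473 to 596 CPM in pooled neuroblasts and 0.28 to 0.60 in neurons. The neuron gene n-syb lay at 2962 and 3284 CPM in neurons, and the glia gene repo at 544 and 592 CPM in glia. Dots are libraries and the short line is the group mean, on a log axis of CPM plus 0.1.

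The second comparison asked which genes tell pooled neuroblasts from glia. Of the lists, 9 of 17 stem cell factors, 21 of 43 cell cycle genes and 5 of 25 oxidative phosphorylation genes were higher in neuroblasts, and 21 of 30 glial genes were higher in glia. The first 3 list calls were lost with an estimated correlation (adjusted p = 0.309, 0.233 and 0.244). Glia also held transcripts of collagen, scavenger receptor and lipid carrier genes that are otherwise known from blood cells and fat body. Of 9855 genes tested 690 were higher and 1339 lower in neuroblasts, a split that turned round to 5648 higher and 249 lower with scaling by spike-in counts per cell. On the TPM values with limma the split was 1255 higher and 1094 lower. The median over all genes was -0.00 with the main scaling, -0.17 with RLE scaling, 0.33 on TPM values and 3.45 with the spike-in scaling.

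The identity gene wor stood at 512 ± 62.1 CPM in neuroblasts (SD, n = 3) and 14.2 ± 3.72 in glia (SD, n = 2), a log2 change of 5.17 ± 0.42 (SE, adjusted p = 9.45e-05). The proneural ase rose by 4.96, grh by 5.43 and the orphan receptor gene tll by 5.73. Of 17 neuroblast identity factors 9 rose, 1 fell and 7 did not pass, against 12 up and 2 down when adjusted over the list alone. Kr was the member that fell, by 5.62. As a list they had adjusted p = 7.50e-05, and adjusted p = 0.309 with an estimated correlation. The gene dpn stood at 454 ± 33.0 CPM against 74.7 ± 93.6 and did not pass (adjusted p = 0.0876), though it passed in 7 of 13 alternatives. The adaptor mira (319 ± 20.97 against 83.1 ± 104 CPM, adjusted p = 0.255) did not pass either. In the 2 glia libraries dpn stood at 153.7 and 9.13 CPM and mira at 170.7 and 10.7. Of 43 cell cycle genes 21 rose (27 adjusted over the list alone) and 22 did not pass (adjusted p = 1.76e-11, and adjusted p = 0.233 with an estimated correlation). CycB3 stood at 1401 ± 263 against 42.5 ± 4.92 CPM, fzy rose by 3.93, the condensin gene SMC2 by 3.98 and E2f by 1.74. Of 25 oxidative phosphorylation genes 5 rose (15 adjusted over the list alone) and 20 did not pass (adjusted p = 6.56e-06, and adjusted p = 0.244 with an estimated correlation). Among them ATPsyn-beta rose by 1.50, CoVb by 2.47, ND42 by 3.81 and RFeSP by 2.98. The homeobox gene oc stood at 126 ± 5.59 against 1.04 ± 1.01 CPM and the zinc finger gene disco at 52.2 ± 20.3 against 0.403 ± 0.363. The genes Mes4, CG13894, CG30467 and Egm had 3 or fewer counts in glia and were 144-fold (49.2 to 701), 400.2-fold (71.6 to 15824), 157-fold (43.3 to 1299) and 134-fold (36.9 to 1108) higher in neuroblasts, with counting intervals in brackets.

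The glial master gene repo (FBgn0011701, chromosome 3R, 14061916 to 14065324 in dm3) stood at 2.22 ± 0.203 CPM in neuroblasts and 524 ± 26.1 in glia, a log2 change of -7.88 ± 0.63 (adjusted p = 9.45e-05). Of 30 glial genes 21 fell in neuroblasts and 9 did not pass, and when adjusted over the list alone 24 fell and 1 rose. The list call had adjusted p = 4.14e-12, and adjusted p = 0.0210 with an estimated correlation. With spike-in scaling the median of the glial list moved from -3.65 to -0.08, and 8 of its genes were then higher and 11 lower in neuroblasts, while relative to the median over all genes it went from -3.65 to -3.53. Glutamine synthetase gene Gs2 stood at 658 ± 288 CPM in glia, the adhesion gene wrapper (chromosome 2R, 18267017 to 18270191 in dm3) at 359 ± 0.0749 and Obp44a (chromosome 2R, 4021875 to 4022588 in dm3) at 7279 ± 3686. Octbeta2R, an octopamine receptor gene, had no count in neuroblasts and was at least 275-fold higher in glia. The RNA-binding gene bru-2 changed by -9.39. The adhesion gene hbs and the genes CG10126, CG31235 and CG10962 had 3 or fewer counts in neuroblasts and were 1050-fold (188 to 41549), 924-fold (255 to 7640), 822-fold (281 to 3991) and 922-fold (165 to 36488) higher in glia, with the call of CG10962 lost in 7 of 13 alternatives.

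Of 8 blood cell genes 5 fell in neuroblasts and 3 did not pass, and when adjusted over the list alone 5 fell and 1 rose. Their call had adjusted p = 0.0340, and adjusted p = 0.421 with an estimated correlation. The collagen IV genes Cg25C and vkg stood at 248 ± 192 and 86.2 ± 66.1 CPM in glia against 2.81 ± 1.02 and 2.16 ± 1.05 in neuroblasts. The phagocytosis receptor gene nimC1 had no count in neuroblasts and stood at 3.87 ± 1.75 CPM in glia, a call lost in 9 of 13 alternatives. The scavenger receptor gene crq stood at 194 ± 19.6 CPM in glia against 59.8 ± 13.6 (adjusted p = 0.0235), but it was higher in neuroblasts by 1.83 (adjusted p = 0.0198) with spike-in scaling, the reverse direction, where the median over all genes was 3.45 and crq so stayed below it. The call was lost in 6 more of 13 alternatives. Of 5 fat body genes 2 fell in neuroblasts (3 adjusted over the list alone) and 3 did not pass (adjusted p = 0.0798, and adjusted p = 0.299 with an estimated correlation). The lipophorin gene Rfabg (chromosome 4, 1085538 to 1096830 in dm3) stood at 4240 ± 3201 CPM in glia against 27.9 ± 0.915, and the insulin-like gene Ilp6 at 125 ± 43.6 against 2.00 ± 0.581. The spike-in scaling moved the medians of these lists from -3.94 to -0.22 for blood cell genes and from -5.74 to -2.37 for fat body genes. Age again differed with cell type, the 2 glia libraries correlated at r = 0.645, and CR41602 and CR40677 held 22.7 ± 4.05% of gene counts in glia. The neuronal n-syb stood at 37.0 ± 17.4 CPM in glia against 1.50 ± 0.243 in neuroblasts.

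The third comparison asked which genes tell neurons from glia. Of the lists, 29 of 35 synapse genes and 8 of 12 glycolysis genes were higher in neurons, and 23 of 30 glial genes and 9 of 15 Notch genes were higher in glia. The list calls of the glycolysis genes (adjusted p = 0.271) and the Notch genes (adjusted p = 0.0644) were lost with an estimated correlation. Of 9855 genes tested 923 were higher and 1061 lower in neurons, and with scaling by spike-in counts per cell 2789 were higher and 465 lower. The median over all genes was -0.23 with the main scaling, -0.18 with RLE scaling and 1.52 with the spike-in scaling.

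The vesicle gene n-syb stood at 3045 ± 300.1 CPM in neurons and 37.0 ± 17.4 in glia (SD, n = 2 each), a log2 change of 6.36 ± 0.42 (SE, adjusted p = 6.35e-05). The active zone gene Rim (chromosome 3R, 13703637 to 13742300 in dm3) stood at 1847 ± 18.3 CPM and the potassium channel gene Shab at 1555 ± 228, each with no count in glia. With the floor of 3 counts they were at least 7924-fold and at least 6465-fold higher. The Shaker regulator gene qvr, the convertase chaperone gene 7B2 and CG42750 also had no count in glia and stood at 726, 516 and 550.0 CPM in neurons. The hormone gene Akh stood at 549 ± 775 CPM, almost all from a single neuron library, and its call was lost in 6 of 11 alternatives. Of 35 genes of neuronal differentiation and synapse 29 rose, 2 fell and 4 did not pass, with 30 up and 2 down when adjusted over the list alone. The group had adjusted p = 1.06e-25, and adjusted p = 0.0423 with an estimated correlation. Members that rose included Rab3 (log2 change 11.32), Appl (9.75), cpx (6.61) and elav (2.54), while pros and Dscam fell by 5.00 and 1.49. Of 12 glycolysis genes 8 rose (9 adjusted over the list alone) and 4 did not pass (adjusted p = 1.04e-06, and adjusted p = 0.271 with an estimated correlation). The aldolase gene Ald stood at 4497 ± 121 against 326 ± 137 CPM, the lactate dehydrogenase gene ImpL3 at 626 ± 108 against 7.89 ± 4.16, and Eno and PyK rose by 2.49 and 2.85.

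The ecdysone-induced gene ImpE1 (chromosome 3L, 8365505 to 8373250 in dm3) stood at 3461 ± 271 CPM in glia with no count in neurons, so it was at least 12228-fold higher in glia. The genes nimA, bbg, Idgf3, Idgf4 and Tep2 had no count in neurons and stood at 1312, 639.6, 626, 684 and 661 CPM in glia. Of 30 glial genes 23 fell in neurons (23 adjusted over the list alone) and 7 did not pass (adjusted p = 4.28e-19, and adjusted p = 0.0110 with an estimated correlation). The glial factor repo stood at 524 ± 26.1 CPM in glia against 0.276 ± 0.391 in neurons, a ratio of 2782-fold (769.7 to 22974). The innexin gene ogre changed by -8.60, wrapper by -8.20 and Obp44a by -7.96. Of 15 Notch targets and pathway genes 9 fell in neurons (12 adjusted over the list alone) and 6 did not pass (adjusted p = 4.29e-06, and adjusted p = 0.0644 with an estimated correlation). Here E(spl)mbeta-HLH (436 ± 134 CPM in glia) and E(spl)m3-HLH (100.3 ± 56.1) had no count in neurons, and the glycosyltransferase gene fng changed by -8.09. Stem cell genes were seen in glia too, with wor at 14.2 ± 3.72 CPM, ase at 5.44 ± 0.241 and dpn at 74.7 ± 93.6, the last at 153.7 CPM in a single library and 9.13 in the other. The adaptor mira (5.26 ± 6.63 against 83.1 ± 104 CPM, adjusted p = 0.0680) did not pass. Each side had 2 libraries, which correlated at r = 0.710 for neurons and 0.645 for glia.

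The fourth comparison asked how mushroom body neuroblasts differ from pooled neuroblasts of all lineages. Mushroom body neuroblasts had more transcript of the lineage factors retn and Rx, far less of SoxN and slp1, and less of the temporal factor Syp. Of 9249 genes tested 825 were higher and 505 lower. With scaling by spike-in counts per cell 293 were higher and 870 lower, and the median over all genes moved from -0.01 to -0.68.

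The ARID factor gene retn (FBgn0004795, chromosome 2R, 19520135 to 19542343 in dm3) stood at 523 ± 74.0 CPM in mushroom body neuroblasts and 33.9 ± 8.96 in pooled neuroblasts (SD, n = 3 each), a log2 change of 3.95 ± 0.40 (SE, adjusted p = 5.79e-05). The homeobox gene Rx (chromosome 2R, 16804285 to 16824537 in dm3) rose by 3.18, ey by 2.08 and tll by 1.04. Of 14 mushroom body lineage genes 6 rose, 2 fell and 6 did not pass, with 7 up and 2 down when adjusted over the list alone. As a group they had adjusted p = 0.0194, and adjusted p = 0.211 with an estimated correlation. The fork head gene slp1 fell from 24.2 ± 9.52 to 0.0780 ± 0.135 CPM, a ratio of 291-fold (52.1 to 11516). Of 15 temporal genes 2 rose, 2 fell and 11 did not pass, with the same counts when adjusted over the list alone (adjusted p = 0.00823, and adjusted p = 0.385 with an estimated correlation). The RNA-binding gene Syp (chromosome 3R, 16582451 to 16631963 in dm3) stood at 1593 ± 135 against 14963 ± 2279 CPM (log2 change -3.23 ± 0.12), br changed by -2.39, lin-28 by 2.57 and Lin29 by 0.87. The temporal genes Imp (-0.16, adjusted p = 0.428) and chinmo (0.26, adjusted p = 0.430) did not pass.

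The SoxB gene SoxN (chromosome 2L, 8825625 to 8829670 in dm3) stood at 1.99 ± 1.18 CPM against 271 ± 38.6 (log2 change -7.06 ± 0.25, adjusted p = 2.74e-16). The genes eya and CG18446 changed by -6.10 and -7.09, and run and dmrt99B were 387-fold (69.2 to 15299) and 79.3-fold (27.0 to 386) lower by counting intervals. Sp1 had no count in mushroom body neuroblasts and stood at 14.7 ± 1.82 CPM in the pool. On the higher side Shroom stood at 457 ± 145 against 3.50 ± 0.696 CPM and the clock gene tim (chromosome 2L, 3501048 to 3507639 in dm3) at 206 ± 67.8 against 2.23 ± 1.71. The genes CG15414, Cyp28d2 and CG8850 rose by 7.38, 6.47 and 6.17, and Cyp28a5 was 709-fold (126 to 28079) higher. Of 11 optic lobe and photoreceptor genes 2 rose (trp by 5.52 and dpp by 3.33, the latter lost in 8 of 13 alternatives), 2 fell (scro and ogre) and 7 did not pass. The counts adjusted over the list alone were the same, the call had adjusted p = 0.668, and the list median turned from 0.35 to -0.31 with spike-in scaling as all genes shifted, while relative to the median over all genes it was 0.36 and 0.37. The marker ase fell by 0.57 (adjusted p = 0.0455), a call lost in 9 of 13 alternatives, while toy, dac, vvl, acj6 and btd did not pass. As the pool is labelled as all neuroblasts, each change is measured against a mixture. Genotypes and drivers of the GFP label are not given. In this and the other lineage comparisons a difference in strain so cannot be told from a difference in lineage.

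The fifth comparison asked how antennal lobe neuroblasts differ from pooled neuroblasts. They had more transcript of the patterning factors ems, mid and hkb and almost none of tll, salm and AP-2. Of 9249 genes tested 925 were higher and 649 lower. Scaled by spike-in counts per cell, 218 were higher and 243 lower, on TPM values with limma 385 were higher and 400 lower, and the median over all genes moved from -0.00 to -0.28.

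The homeobox gene ems (FBgn0000576, chromosome 3R, 9727581 to 9730346 in dm3) stood at 95.9 ± 15.9 CPM against 12.8 ± 8.15 in the pool (SD, n = 3 each), a log2 change of 2.90 ± 0.47 (SE, adjusted p = 4.77e-04). The T-box gene mid (chromosome 2L, 5461641 to 5466829 in dm3) rose by 4.77, hkb by 5.97, Dr by 2.51 and D by 1.54. Of 14 antennal lobe lineage genes 3 rose, 3 fell and 8 did not pass, with 4 each way when adjusted over the list alone. The list median (-0.28) and mean (-0.36) were below 0 while the list test pointed up and did not pass (adjusted p = 0.560, and adjusted p = 0.629 with an estimated correlation). A member that fell was run, from 32.4 ± 7.62 to 7.79 ± 2.505 CPM. Of 15 temporal genes 8 rose, 1 fell and 6 did not pass, with the same counts when adjusted over the list alone (adjusted p = 0.00182, and adjusted p = 0.308 with an estimated correlation). Fewer passed with spike-in scaling (1 higher, 1 lower) and with limma on TPM values (2 higher, 1 lower). Imp rose by 0.75 to 16922 ± 3161 CPM, svp by 1.40 and grh by 0.68, while cas changed by -2.39. Syp (0.01, adjusted p = 0.970) and chinmo (0.43, adjusted p = 0.148) did not pass.

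The orphan receptor gene tll (chromosome 3R, 26678037 to 26680095 in dm3) stood at 2.73 ± 0.263 CPM against 144 ± 14.8 (log2 change -5.71 ± 0.22, adjusted p = 1.31e-15). The spalt gene salr changed by -6.26, erm by -6.37 and CG18446 by -5.25. The other spalt gene salm was 1694-fold (304 to 66961) lower and AP-2 635-fold (114 to 25132) lower by counting intervals. The type II gene Sp1 fell from 14.7 ± 1.82 to 0.177 ± 0.0639 CPM, pnt from 105 ± 23.9 to 23.9 ± 11.03 and toy from 79.1 ± 8.59 to 11.6 ± 2.07. Shroom stood at 529 ± 194 against 3.50 ± 0.696 CPM and the retrovirus-like gene Arc1 at 159 ± 40.4 against 4.98 ± 2.02. The peptide receptor gene Dh44-R1 and the phosphatase gene Ptp52F rose by 5.86 and 5.57. Of 11 optic lobe and photoreceptor genes 2 rose (3 adjusted over the list alone), 1 fell and 8 did not pass (adjusted p = 0.239). They were trp (4.03) and Fas3 (1.46) on the higher side and scro on the lower, with no count in antennal lobe neuroblasts, and the call of Fas3 was lost in 9 of 13 alternatives. The markers ase, ey, dac, vvl, acj6 and btd did not pass.

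The sixth comparison asked how type II neuroblasts differ from pooled neuroblasts. Type II neuroblasts are known for passing through intermediate progenitors and for lacking the type I markers ase and pros. Both genes were far lower in the type II libraries, and pnt and Sp1 were higher. Of 9249 genes tested 344 were higher and 204 lower. With spike-in counts per cell as the scale 1036 were higher and 66 lower, on TPM values with limma 98 were higher and 119 lower, and the median over all genes moved from -0.02 to 0.78 with the spike-in.

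The ETS factor gene pnt (FBgn0003118, chromosome 3R, 19116826 to 19120960 in dm3) stood at 692 ± 79.0 CPM against 105 ± 23.9 in the pool (SD, n = 3 each), a log2 change of 2.72 ± 0.33 (SE, adjusted p = 3.42e-04). The zinc finger gene Sp1 (chromosome X, 9623681 to 9649831 in dm3) rose by 3.12, the homeobox gene Dll by 2.77 and tll by 1.19, while btd (2.55, adjusted p = 0.0755) did not pass. Of 16 type II lineage genes 6 rose, 4 fell and 6 did not pass, with 7 up and 5 down when adjusted over the list alone. Its test pointed up (adjusted p = 0.0154, and adjusted p = 0.165 with an estimated correlation), with a median of 0.46 and a mean of -0.24, opposite in sign. The members that fell were erm and opa, known from intermediate progenitors, and grn and bi, with changes of -5.55, -4.49, -1.81 and -3.36. All 3 type I markers fell, also when adjusted over the list alone (adjusted p = 1.16e-35, and adjusted p = 0.00135 with an estimated correlation). The proneural ase stood at 4.50 ± 1.32 against 176 ± 35.4 CPM, pros (chromosome 3R, 7198510 to 7220799 in dm3) at 101 ± 33.9 against 1310 ± 237 and l(1)sc at 5.47 ± 3.96 against 40.3 ± 3.86.

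Of 15 temporal genes 2 rose, 1 fell and 12 did not pass, with 3 up and 2 down when adjusted over the list alone (adjusted p = 0.167). Syp rose by 1.06 to 31267 ± 3191 CPM, br by 1.09, and lin-28 fell from 22.2 ± 5.00 to 2.17 ± 0.585 CPM. Imp (-0.36, adjusted p = 0.0941) and chinmo (-0.41, adjusted p = 0.286) did not pass. The lactate dehydrogenase gene ImpL3 stood at 269 ± 46.3 against 3.39 ± 1.15 CPM and the pigment transporter gene w at 661 ± 356 against 39.3 ± 7.36. Genotypes are not given, so transcripts of w from a transgene cannot be set apart from those of the gene. CG10936, CG13196, CG1887 and CG34396 rose by 5.50, 4.30, 4.15 and 3.85. The zinc finger gene disco-r had no count in type II neuroblasts and stood at 50.7 ± 13.9 CPM in the pool. The gene salr was 330.2-fold (59.0 to 13065) lower by its counting interval. The genes oc, salm, bnb and Tl changed by -5.86, -6.79, -6.63 and -5.67, toy by -4.14 and dac by -4.45. Of 11 optic lobe and photoreceptor genes trp alone rose (3.96), also when adjusted over the list alone, and 10 did not pass (adjusted p = 0.845). As trp rose against the pool in the mushroom body and antennal lobe lineages too, its rise is not particular to type II.

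The seventh comparison asked which genes set mushroom body neuroblasts apart from both the antennal lobe and the type II lineages. A gene was called where it passed against each of the 2 with the same sign, and the smaller change is given. List tests in this and the next comparisons set the lineage against the mean of the other 2. The lineage genes retn, Rx and ap marked mushroom body neuroblasts, SoxN, ct and slp2 were low in them, and many ribosomal protein transcripts were somewhat higher with the main scaling, while with spike-in scaling their median turned below 0 along with that of all genes. Their share of gene counts was 7.49 ± 0.900% in the standard mushroom body libraries used here, but 5.67 ± 0.857% and 4.75 ± 0.632% in those with the wait and the washes, beside 4.31 ± 0.415% in antennal lobe, 5.11 ± 0.734% in type II and 5.57 ± 0.561% in pooled neuroblasts. Of 9249 genes tested 172 were higher and 206 lower. With scaling by spike-in counts per cell 24 were higher and 192 lower, on TPM values with limma 134 were higher and 88 lower, and the median over all genes, of the mean of the 2 changes, moved from 0.05 to -0.89 with the spike-in.

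The factor gene retn stood at 523 ± 74.0 CPM against 4.55 ± 1.06 in antennal lobe and 3.99 ± 4.02 in type II neuroblasts (SD, n = 3 each), a log2 change of 6.84 ± 0.48 (SE, adjusted p = 2.47e-06). Rx rose by 5.95, the LIM homeobox gene ap by 5.06 and the phosphatase gene wun2 by 6.05. The genes Cpr76Bc and CG5630 rose by 6.14 and 4.95. Of 14 mushroom body lineage genes 7 rose, 2 fell and 5 did not pass, with 8 up and 2 down when adjusted over the list alone. The list test gave adjusted p = 2.97e-15, and adjusted p = 0.00931 with an estimated correlation. The Pax6 gene toy rose by 2.42 and dac by 1.97, and the other Pax6 gene ey rose by 1.39, a call lost in 11 of 16 alternatives. The member slp2 changed by -5.91 and slp1 was 169-fold (30.0 to 6698) lower by its counting interval. The SoxB genes SoxN and D stood at 1.99 ± 1.18 and 6.88 ± 0.867 CPM, against 499 ± 20.8 and 292 ± 73.9 in antennal lobe neuroblasts. The homeobox gene ct stood at 22.03 ± 8.40 CPM against 845 ± 103 and 695 ± 60.5.

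Of 15 temporal genes 1 rose, 4 fell and 10 did not pass, with 1 up and 5 down when adjusted over the list alone (adjusted p = 5.05e-07, and adjusted p = 0.184 with an estimated correlation). Syp stood at 1593 ± 135 CPM against 15051 ± 1010 in antennal lobe and 31267 ± 3191 in type II neuroblasts, and lin-28 rose by 1.48. The hormone response genes br, EcR, Eip93F and E23 changed by -2.71, -1.24, -4.20 and -4.19. Of 87 cytoplasmic ribosomal protein genes 44 rose (68 adjusted over the list alone) and 43 did not pass, but the list median turned from 0.57 to -0.41 with spike-in scaling, where no member passed. Relative to the median over all genes the list stood at 0.53 with the main scaling and 0.48 with the spike-in, and limma on TPM values called 4 of 89 genes higher. The camera test gave adjusted p = 2.52e-27, and adjusted p = 0.206 with an estimated correlation. RpL32 stood at 718 ± 65.5 CPM against 379 ± 50.9 and 424 ± 51.4, and RpL37A, RpL39 and RpLP0 rose by 0.85, 0.86 and 0.66. The markers vvl, acj6 and Sp1 did not pass, and ase, chinmo, Imp, pnt and btd lay between the other 2 lineages or apart from only 1 of them.

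**Figure D3:**
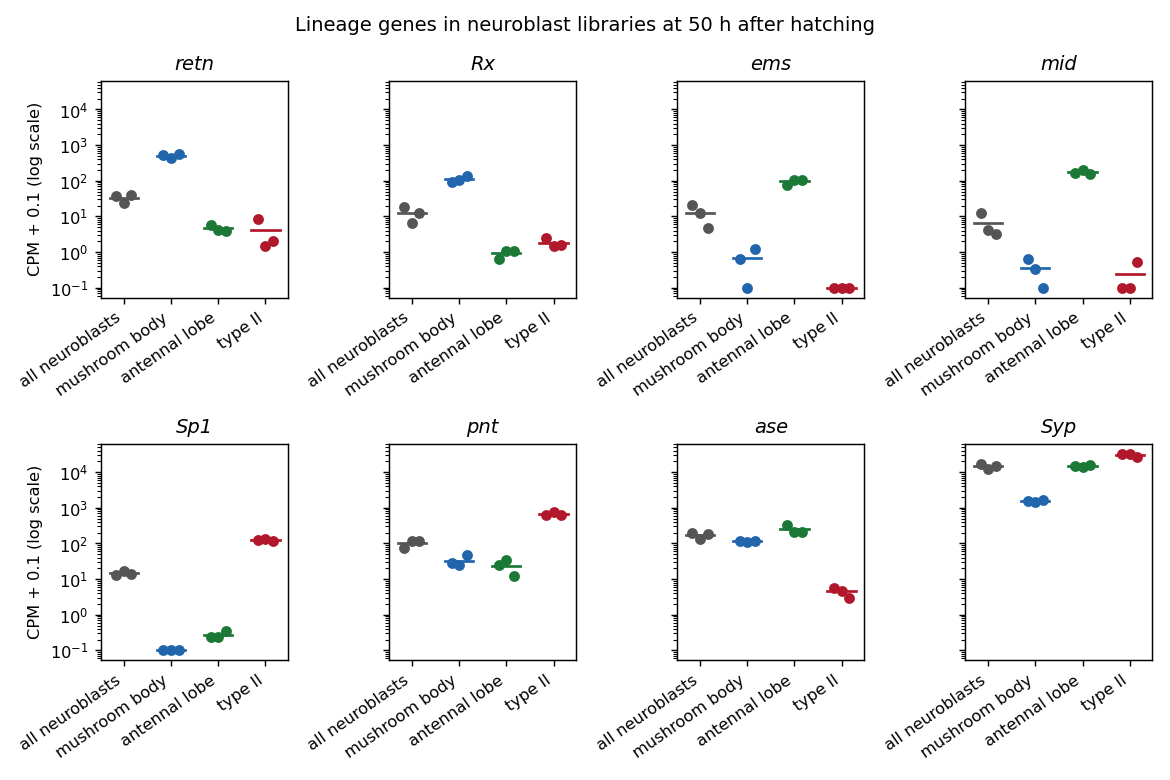
Genes of the neuroblast lineages in each library. The factor gene retn lay at 427 to 552 CPM in mushroom body neuroblasts, mid at 160 to 207 CPM in antennal lobe neuroblasts and Sp1 at 114 to 136 CPM in type II neuroblasts. Syp lay at 1418 to 1661 CPM in mushroom body and 26978 to 33290 CPM in type II neuroblasts. Dots are libraries and the short line is the group mean, on a log axis of CPM plus 0.1.

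The eighth comparison asked which genes set antennal lobe neuroblasts apart from the mushroom body and type II lineages. They carried ems, mid, hkb and Dr, had little tll, and had lower transcripts of glycolysis and oxidative phosphorylation. Of 9249 genes tested 168 were higher and 190 lower, against 24 higher and 53 lower with scaling by spike-in counts per cell, where the median over all genes, of the mean of the 2 changes, moved from 0.01 to -0.33.

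The homeobox gene ems stood at 95.9 ± 15.9 CPM against 0.583 ± 0.585 in mushroom body neuroblasts, with no count in type II neuroblasts, a log2 change of 7.30 ± 0.67 (SE, adjusted p = 8.85e-07). The T-box gene mid stood at 178 ± 26.8 CPM and was 699-fold (239 to 3393) higher by its counting interval, and Dr and hkb rose by 5.70 and 6.08. Of 14 antennal lobe lineage genes 3 rose, the same when adjusted over the list alone, and 11 did not pass (adjusted p = 4.23e-16, and adjusted p = 0.00153 with an estimated correlation). They were ems, Dr and D (1.80). Of 117 patterning transcription factors 12 rose (14 adjusted over the list alone), 4 fell and 101 did not pass, and the list median turned from 0.24 to -0.02 with spike-in scaling as all genes shifted, while relative to the median over all genes it went from 0.23 to 0.31. As a set they had adjusted p = 8.94e-07, and adjusted p = 0.0959 with an estimated correlation. The orphan receptor gene tll stood at 2.73 ± 0.263 CPM against 295 ± 43.2 and 327 ± 61.8, a change of -6.74. The genes CG42324 and dpr17 rose by 3.63 and 3.84, Imp by 0.91 and ase by 1.07.

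Of 12 glycolysis genes 9 fell (10 adjusted over the list alone) and 3 did not pass (adjusted p = 3.52e-18, and adjusted p = 0.0368 with an estimated correlation). ImpL3 stood at 13.3 ± 5.30 CPM against 188 ± 102 in mushroom body and 269 ± 46.3 in type II neuroblasts. In pooled neuroblasts ImpL3 was lower still, at 3.35 CPM scaled over all 22 libraries, so antennal lobe neuroblasts were not the lowest neuroblast group. Gapdh1 (209 ± 10.0 against 496 ± 50.3 and 501 ± 30.5 CPM) changed by -1.25, Pgi by -1.58 and Pglym78 by -1.30. Of 25 oxidative phosphorylation genes 14 fell (17 adjusted over the list alone) and 11 did not pass (adjusted p = 7.69e-13, and adjusted p = 0.0190 with an estimated correlation). ND42 changed by -1.05, ATPsyn-Cf6 by -0.86, CoIV by -0.75 and ATPsyn-b by -0.74. Both medians stayed below 0 with spike-in scaling (-1.32 and -1.04), where all genes shifted down as well. Relative to the median over all genes they went from -0.98 to -0.99 and from -0.75 to -0.71. With spike-in scaling only 1 glycolysis gene and no oxidative phosphorylation gene fell. With limma on TPM values 5 of 12 glycolysis genes and 0 of 25 oxidative phosphorylation genes fell. The sugar transporter gene Tret1-1 stood at 28.5 ± 5.83 CPM against 395 ± 54.2 and 519.7 ± 109. In pooled neuroblasts Tret1-1 stood at 102 CPM scaled over all 22 libraries. The genes asparagine-synthetase, CG10960 and pan, the fly TCF, changed by -3.08, -2.17 and -2.66. Of GO processes, glycolytic process had 8 of its 22 genes lower (adjusted p = 7.56e-06) and central nervous system development had 12 of 75 higher (adjusted p = 6.45e-06).

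The ninth comparison asked which genes set type II neuroblasts apart from the mushroom body and antennal lobe lineages. They carried Sp1, pnt, btd, Dll, Six4 and Optix and had little ase and pros transcript. Of 9249 genes tested 129 were higher and 214 lower. Scaled by spike-in counts per cell, 2780 were higher and 39 lower, and the median over all genes, of the mean of the 2 changes, moved from 0.01 to 1.27.

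The zinc finger gene Sp1 stood at 128 ± 11.5 CPM (SD, n = 3), with no count in mushroom body and 0.177 ± 0.0639 in antennal lobe neuroblasts, a log2 change of 9.32 ± 0.42 (SE, adjusted p = 6.60e-13). The ETS gene pnt stood at 692 ± 79.0 CPM against 34.1 ± 12.6 and 23.9 ± 11.03. Of 16 type II lineage genes 6 rose and 10 did not pass, while 6 rose and 1 fell when adjusted over the list alone (adjusted p = 2.24e-24, and adjusted p = 0.00135 with an estimated correlation). The homeobox gene Dll stood at 55.8 ± 8.24 CPM against 0.395 ± 0.359 and 0.255 ± 0.329. The zinc finger gene btd rose by 4.90 and the homeobox genes Six4, Optix and Hmx by 5.67, 5.61 and 5.55. CG10936 rose by 5.27 and Syp by 1.05. All 3 type I markers fell, also when adjusted over the list alone (adjusted p = 1.72e-27, and adjusted p = 0.00174 with an estimated correlation). ase stood at 4.50 ± 1.32 CPM against 119 ± 6.08 in mushroom body and 248 ± 60.8 in antennal lobe neuroblasts, pros changed by -3.61 and l(1)sc by -1.76. The genes lin-28, SoYb, Shroom, dac, CG31551, toy and chinmo changed by -4.45, -4.46, -3.88, -3.67, -3.48, -1.38 and -0.66. The calls of l(1)sc and chinmo were lost in 10 and 9 of 16 alternatives.

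Of 12 glycolysis genes 4 rose, the same when adjusted over the list alone, and 8 did not pass (adjusted p = 5.50e-13, and adjusted p = 0.0617 with an estimated correlation). They were Ald (1387 ± 97.1 against 895 ± 148 and 599.9 ± 98.1 CPM), Hex-A, Gapdh2 and Eno, with changes of 0.63, 0.56, 0.51 and 0.44, and the call of Hex-A was lost in 8 of 16 alternatives. Of 43 cell cycle genes 2 rose, the same when adjusted over the list alone, and 41 did not pass (adjusted p = 0.0220, and adjusted p = 0.417 with an estimated correlation). These were the phosphatase gene stg (0.66) and the cyclin gene CycB (0.56). Both list tests set type II against the mean of the other lineages. The low antennal lobe values so enter the glycolysis call, which does not show type II above each lineage. With spike-in scaling 12 glycolysis and 33 cell cycle genes rose, and with limma on TPM values 0 of either. The spike-in scaling rests on type II libraries whose RNA per cell ran from 3.31 to 8.87. Imp (-0.20, adjusted p = 0.350) and ey (-1.18, adjusted p = 0.0906) did not pass.

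The tenth comparison asked whether the transcriptome of mushroom body neuroblasts changed in the libraries labelled with a 2 h wait. Little changed gene by gene. Ribosomal protein transcripts were lower in the list test, a call that was lost with an estimated correlation. Of 8766 genes tested with edgeR 2 fell and 727 passed unadjusted, while DESeq2 called 13 higher and 25 lower and limma on TPM values called 1 other gene. The spike-in scaling called 1 higher and 3 lower. CG32037 (chromosome 3L, 9482602 to 9485315 in dm3) fell from 99.4 ± 12.8 to 23.8 ± 7.31 CPM (SD, n = 3 each), a log2 change of -2.06 ± 0.30 (SE, adjusted p = 0.00313). The microtubule plus-end gene chb (chromosome 3L, 21170961 to 21176378 in dm3) fell from 491 ± 70.8 to 253 ± 29.1 CPM, a log2 change of -0.96 ± 0.14 (adjusted p = 0.00313). Of 87 cytoplasmic ribosomal protein genes all 87 did not pass over all genes, and 47 fell when adjusted over the list alone. Their median was -0.38, and -0.26 with spike-in scaling (adjusted p = 7.67e-30, and adjusted p = 0.244 with an estimated correlation). Of 30 genes of heat shock and dissociation stress none passed, also when adjusted over the list alone (adjusted p = 0.910, and adjusted p = 0.953 with an estimated correlation). Their median was -0.00 and turned to 0.03 with spike-in scaling (-0.01 and -0.11 relative to all genes), their mean was 0.04 and the test pointed down.

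The eleventh comparison asked whether mushroom body neuroblasts labelled with 3 washes differed from the standard ones. Transcripts of ribosomal proteins and of several heat shock proteins were lower with the main scaling, while both list medians turned above 0 with spike-in scaling along with that of all genes, and sna and 2 Notch targets were higher. All 3 list calls were lost with an estimated correlation (adjusted p = 0.0910, 0.162 and 0.0644). Of 8766 genes tested 14 were higher and 59 lower with edgeR, and 50 higher and 84 lower with DESeq2. With spike-in counts per cell as the scale 2126 were higher and 8 lower, and the median over all genes moved from 0.01 to 0.77. Limma on TPM values called 3 genes, and 0 of them were among the 73 called with edgeR.

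The ribosomal stalk gene RpLP2 (FBgn0003274, chromosome 2R, 12473639 to 12474237 in dm3) stood at 293 ± 49.0 CPM against 646 ± 90.1 (SD, n = 3 each), a log2 change of -1.14 ± 0.16 (SE, adjusted p = 0.00240). Of 87 cytoplasmic ribosomal protein genes 46 fell (75 adjusted over the list alone) and 41 did not pass, but their median turned from -0.64 to 0.14 with spike-in scaling, where 4 rose. Relative to the median over all genes the list stood at -0.65 with the main scaling and -0.63 with the spike-in. Its median was also below 0 after the 2 h wait (-0.38), against the same 3 standard libraries. Those had the highest share of ribosomal protein counts of all groups. The list call had adjusted p = 4.77e-83, and adjusted p = 0.0910 with an estimated correlation. RpL18, RpL7A, RpL26, RpL35 and RpLP1 changed by -1.26, -1.05, -0.95, -0.89 and -1.09, with the call of RpLP1 lost in 9 of 13 alternatives. Of 30 genes of heat shock and dissociation stress 4 fell (6 adjusted over the list alone) and 26 did not pass, and their median turned from -0.36 to 0.41 with spike-in scaling (-0.37 and -0.36 relative to all genes). That call had adjusted p = 7.97e-08, and adjusted p = 0.162 with an estimated correlation. The chaperone genes Hsp26, DnaJ-1, Hsp23 and Hsp83 changed by -0.87, -0.94, -0.80 and -0.52, but of 13 alternatives 7 lost the call of DnaJ-1, 10 that of Hsp23 and 8 that of Hsp83. Of 15 Notch targets and pathway genes 2 rose (7 adjusted over the list alone) and 13 did not pass (adjusted p = 8.07e-08, and adjusted p = 0.0644 with an estimated correlation). With spike-in scaling 11 of 15 rose, as all genes shifted up, and with limma on TPM values 0 of 16. E(spl)mbeta-HLH stood at 79.6 ± 28.1 against 26.5 ± 8.36 CPM and E(spl)m7-HLH at 157 ± 29.5 against 62.8 ± 16.6. The Snail family gene sna rose by 1.14, the zinc finger gene shn by 0.90, Tab2 by 1.32 and CG10970 by 2.38, and the calls of Tab2 and E(spl)mbeta-HLH were each lost in 7 of 13 alternatives. The temporal factor gene cas and CG32037 changed by -1.76 and -1.71. Leaving out a single library moved the count of called genes between 6 and 94.

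**Figure D4:**
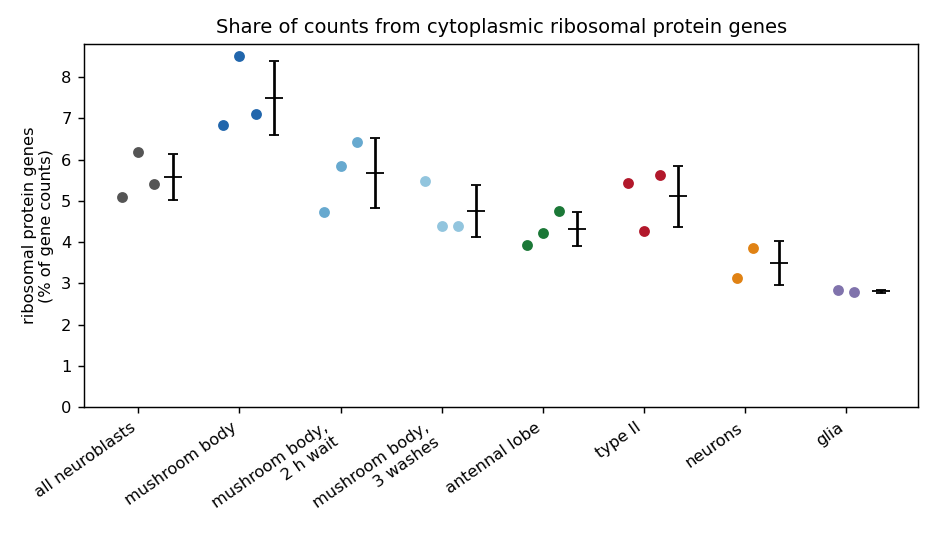
Share of gene counts in each library held by 93 cytoplasmic ribosomal protein genes, of which 87 were tested after 3 washes. Mushroom body neuroblasts stood at 7.49 ± 0.900%, those with a 2 h wait at 5.67 ± 0.857% and those with 3 washes at 4.75 ± 0.632% (SD, n = 3 each), while with spike-in scaling the median change after 3 washes turned from -0.64 to 0.14 (-0.65 and -0.63 relative to all genes). Dots are libraries and the black mark is the mean with its SD.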

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

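The tests of transcript length, of depth in antennal lobe neuroblasts and of fat body and blood cell carry-over were chosen only after the results were seen. Reads outside annotated genes were noted because they lie in data that no comparison used: they came to 19.7% in neurons and 19.39% in glia (group means, n = 2), against 8.87% in pooled neuroblasts, as shares of all counts with ERCC included. ERCC counts were 8.97% of gene plus ERCC counts in glia, 2.70% in neurons and 0.447% in pooled neuroblasts, which lowers the glia value most. The entry with no gene name held up to 17 counts, in antennal lobe library 3.

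Ribosomal protein transcripts were lower after 3 washes, with a median log2 change of -0.641 over 87 genes that turned to 0.14 with spike-in scaling (-0.65 and -0.63 relative to all genes), and the list call was lost with an estimated correlation (adjusted p = 0.0910). Lists of other genes matched on transcript length and level had a median of -0.1924 (95% of lists from -0.245 to -0.122), so the matched genes fell less. How close the matches came was not checked, so the part that length plays is not settled. Thinning all libraries to the smallest total left the median at -0.6503 with 45 genes lower. Dropping the 10 genes that held 29.1% of counts, CR40677 among them, left it at -0.6372. Thinning keeps the expected share of each gene and TMM scaling trims extreme genes, so neither step could move the median much. The thinning shows that the calls do not rest on unequal depth, while calls were not counted after the 10 genes were dropped. Neither step tests differences in input RNA. CR40677 held 10.7 and 9.84% of counts in wash libraries 2 and 3 (ribosomal protein share 4.38% each) and 5.61% in library 1 (5.48%), against 5.35 to 6.71% in standard libraries. The standard libraries used as reference had the highest share of ribosomal protein counts of all groups (7.49%), and those with the wait were lower too (5.67%). Wash libraries (4.75%) lay within the range of antennal lobe, type II and pooled neuroblasts (4.31, 5.11 and 5.57%). Whether the washed or the standard libraries stand apart is so not settled. Handling or a difference between preparations could lie behind the change, and the labels do not separate the 2.

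Oxidative phosphorylation and glycolysis transcripts were lower in antennal lobe neuroblasts than in both other lineages, with a median of -0.791 over 37 genes. Most calls were lost in 2 alternatives. Spike-in scaling called 1 glycolysis and 0 oxidative phosphorylation genes lower, and limma on TPM values 5 and 0. Lists matched on transcript length and level had a median of -0.2064 (95% of lists from -0.338 to -0.0495), so the matched genes fell less. The closeness of these matches was not checked either, so the part of length is not settled. Antennal lobe libraries held 8.37 M gene counts on average against 3.67 M and 5.01 M in mushroom body and type II, and CR43283 held 19.6% of them against 7.16 and 11.4%. Thinning all libraries to the smallest total left the median at -0.7668 with 23 genes lower, as before. Dropping the 10 genes that held 32.3% of counts, CR43283, CR41602 and CR40677 among them, left it at -0.7709. As above, neither step could move the median much. The thinning shows only that the calls do not rest on unequal depth. Calls were not counted after the 10 genes were dropped, so that step does not decide their part. In pooled neuroblasts ImpL3 was lower (3.35 CPM) than in antennal lobe neuroblasts (13.25 CPM), while Tret1-1 was higher (102 against 28.6 CPM). How the 2 lists stand against the pool is not given here. A metabolic difference between the lineages may be the source, as a hypothesis found in these data that was not tested, while preparation day, which the labels do not give, stays open.

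Some blood cell and fat body transcripts, such as Cg25C, vkg and Rfabg, stood higher in glia than in neuroblasts, while the fat body list did not pass (adjusted p = 0.0798) and the blood cell call was lost with an estimated correlation (adjusted p = 0.421). Fat body cells would bring their other abundant transcripts, yet the highest of 6 such genes reached 0.7595% of Rfabg, at 16.4 against 2157 CPM in the first glia library and 2.68 against 6997 in the second. Of 10 blood cell genes 30% passed 10 CPM in both glia libraries, Cg25C (419 and 121 CPM), vkg (145 and 42.5) and crq (197 and 224), and srp (48.1 and 9.60) lay at that level within its 95% counting interval of 7.34 to 12.3. Pxn stood at 1.08 and 0 CPM, Hml at 25.0 and 0.472, and eater and Sr-CI had no count. These values do not decide whether blood cells were carried over, so the source of the collagen transcripts stays open.

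Other splits of the same libraries were counted too. For mushroom body against pooled neuroblasts (1330 genes called, highest other split 0), antennal lobe (1574, highest other 0), type II (548, highest other 2), the 2 h wait (2, highest other 0) and the 3 washes (73, highest other 0), only the real split, 1 of 10, called as many, and 10 splits are too few for a share under 0.05. For each lineage against both others 1 of 100 splits called as many: 378 genes for mushroom body against at most 130, 358 for antennal lobe against at most 180 and 343 for type II against at most 142.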

How the results depend on the processing

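Spike-in scaling of lineage and handling comparisons was added only after the results were seen. All results below are counts of called genes in the order neuroblast against neuron, neuroblast against glia, neuron against glia, mushroom body, antennal lobe and type II against the pool, the same against both other lineages, 2 h wait and 3 washes. RLE scaling kept each count within 1.5 times.

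With all 22 libraries in 1 fit the counts were 4687, 4731, 4618, 493, 396, 140, 114, 75, 91, 0 and 2. This fit has more residual degrees of freedom and a single dispersion trend for all groups, and which of these moved the counts was not tested. Scaling by spike-in counts per cell gave 4129, 5897 and 3254 for cell types, 461 for antennal lobe and 1102 for type II against the pool, 216, 77 and 2819 against both other lineages, and 4 and 2134 for handling. There crq reversed to 1.8295 (adjusted p = 0.0198) in neuroblast against glia, where the median over all genes was 3.45. DESeq2 called 3304 genes in neuroblast against glia, 3351 in neuron against glia, 38 after the wait and 134 after 3 washes. Limma on TPM values called 785 for antennal lobe and 217 for type II against the pool, 222, 125 and 179 against both other lineages, 1 after the wait and 3 after 3 washes. With no low-count filter 59 were called after the wait and 134 after 3 washes. Taking the mean of the 4 standard neuroblast groups in place of the pool gave 5153 against neurons and 5201 against glia. For these moves the cause was not tested.

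No pairing by replicate number was seen. The correlation of deviations ran from -0.0737 to 0.113 for libraries of the same number and from -0.119 to 0.0987 for others. Deviations were taken from means of few libraries, which ties these values to each other. They so cannot exclude shared preparations or days, which the labels do not give. A replicate block gave 1346 in neuroblast against neuron, 788 in neuroblast against glia, 1194 in neuron against glia and 40 after 3 washes, with fewer residual degrees of freedom, and kept the other counts within 1.5 times. Not every library correlated best with its own number.

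Leaving out each library in turn, with a lone remaining neuron or glia library assumed to vary like the other groups, gave 1394 to 2641 genes in neuroblast against neuron, where leaving out pooled neuroblasts 1, 2 and 3 gave 1448, 1433 and 1394. In neuroblast against glia it gave 836 to 2012 (877, 894 and 836 without the same 3), and in neuron against glia 1420 to 2052. Against the pool the ranges were 862 to 1080 for mushroom body (862 without mushroom body 3), 958 to 1454 for antennal lobe (958 and 1023 without pooled neuroblasts 2 and 3, 1012 without antennal lobe 1) and 317 to 501 for type II (343 and 317 without type II 1 and 2). Against both other lineages they were 216 to 311 for mushroom body (216 without mushroom body 2, 245 without type II 2), 206 to 341 for antennal lobe (206 without antennal lobe 1, 237 without mushroom body 2) and 198 to 319 for type II (226 and 198 without type II 2 and 3). After the wait the range was 2 to 6 (6 without wait library 3). After 3 washes it was 6 to 94 (6 and 7 without wash libraries 3 and 2, 11 and 31 without mushroom body 2 and 3).

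Of 253 list tests 120 passed, and 18 passed with the estimated correlation (5 up, 13 down). RNA per cell, taken from pooled neuroblasts alone, had log2 differences of 1.4883 to neurons and 3.3296 to glia, each with exact permutation p = 0.200, the smallest that 10 splits allow. Without division by cell number they were 1.69 and 4.47. Over the named genes and all alternatives 3966 values kept direction and side of the threshold, 314 fell below it, 42 rose above it and 1 reversed. Spike-in scaling of TPM values was not run, as that table holds no ERCC values. Depth limits genes of few counts, and with 2 neuron and 2 glia libraries 22% and 16% of 8-fold and 74% and 66% of 64-fold changes were called in simulated data of neuroblast against neuron and neuron against glia. Far fewer genes changed in those simulated data than were called in the real data, so these rates need not carry over.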

Other observations

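The genes described here were chosen only after their values were seen. The 2 neuron libraries differed in peptide and transmitter genes. Akh stood at 1106 CPM in the first and 0.894 in the second, Fmrf at 2.78 and 5454, Dh44 at 2485 and 10.9, and Vmat at 4065 and 977. Both carried amon (306 and 666 CPM), 7B2 (591 and 467) and IA-2 (9064 and 14740), genes known from peptide processing and secretory granules. Phm stood at 111 and 160 CPM in neurons and 137 and 56.5 in glia. Other peptide-related genes were low in the 2 neuron libraries: dimm at 2.51 and 0 CPM, Crz at 0.557 and 0, Ilp2 at 3.62 and 1.64, and Ilp3 at 0. The muscle-type spectrin repeat gene Msp-300 stood at 5344 to 9652 CPM in mushroom body neuroblasts against 279 to 602 in pooled, 859 to 938 in antennal lobe and 312 to 528 in type II neuroblasts, but it was as high in glia (7845 and 7951) and neurons (6974 and 7856).

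Among lists not described above, ribosome biogenesis and Myc had 11 of 25 genes higher in neuroblasts than in neurons (15 adjusted over the list alone, adjusted p = 1.37e-05, and adjusted p = 0.181 with an estimated correlation). Ganglion mother cell and newborn neuron genes had 6 of 15 higher and 3 lower there (adjusted p = 0.803). Muscle and trachea genes had 4 of 13 lower in neuroblasts than in glia (adjusted p = 0.0745). Of GO processes, translation had 43 of 182 genes higher in mushroom body neuroblasts than in both other lineages (adjusted p = 1.63e-30). That test takes genes as independent, and the ribosomal protein list call of this comparison was lost with an estimated correlation. Limma on TPM values called 4 of 89 ribosomal protein genes higher. With spike-in scaling the median of ribosomal protein genes turned below 0 along with that of all genes. Ion transport had 36 of 68 higher in neurons than in glia (adjusted p = 2.11e-16). In type II neuroblasts glycolytic process had 4 of 22 higher (adjusted p = 0.0122) and brain morphogenesis 5 of 15 lower (adjusted p = 0.00165).

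The pigment transporter gene w stood at 31.7 to 46.3 CPM in pooled neuroblasts and at 252 to 915 in every lineage library. Genotypes are not given, so a transgene that carries w cannot be set apart. Shroom stood at 2.76 to 4.12 CPM in pooled neuroblasts, 5.68 to 57.4 in type II, 316 to 692 in antennal lobe and 356 to 601 in mushroom body neuroblasts. The clock gene tim and its neighbour CG15414 (chromosome 2L, 3480755 to 3491071 in dm3) were both high in mushroom body neuroblasts, tim at 150 to 272 CPM. For Shroom, tim and CG15414 too, a difference in strain between the groups cannot be set apart from lineage.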
